A study of Mus musculus with 12 samples.

How the data were processed

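Tregs of 8 lymph node libraries and OT-I T cells of 3 coculture libraries were measured by Seq-Well with second strand synthesis. Per the series' design text, libraries were made with Nextera XT and sequenced on a NovaSeq, and hashtag libraries on a NextSeq. The gene by cell tables hold raw UMI counts as deposited, and reads were assigned to genes of genome build mm10 per the submitters' processing notes. The aligner, the counting tool, the gene annotation and the rule by which barcodes were kept are not given in the sources used here. The hashtag tables hold raw counts per barcode and hashtag as deposited, and hashtags labelled mice of the tumour-draining groups per the series' design text. Each hashtag was taken as 1 mouse. The TCR table holds consensus sequences with the count of reads behind each, as deposited. Per the labels it covers the lymph node samples, it names no library, and its lowest count was 3. The tools behind it are not given in the sources used here.

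Cells with at least 300 detected genes and under 20% of UMIs on mitochondrial genes were kept, which left out 0 to 4.78% of the barcodes of a library. A minimum of 500 genes removed no further cell. Totals per library ran from 753766 to 18608250 UMIs, and the fewest UMIs of a passing cell were 1047. Cells of each experiment were clustered with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1, leidenalg 0.10.2), and a cluster with 3 markers of another cell type among its top 10 genes was to be left out. No cluster met this. Scrublet, as in scanpy with an expected doublet rate of 0.06, marked under 1% of cells in 10 of the libraries and 6.51% in lung naive library 2, and so has not worked as a doublet count for most of them. A cell was assigned to a mouse when a hashtag had at least 10 counts and at least 60% of its hashtag counts.

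UMIs of passing cells were summed per library and tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr by group, a quasi-likelihood fit on group means, and Benjamini-Hochberg adjustment over the genes tested with a threshold of 0.05. The lymph node fit took all 8 libraries with 4 residual degrees of freedom (11134 genes, common biological coefficient of variation 0.0953), and the coculture fit took 3 libraries with 1 (11784 genes, 0.102). CPM of genes are TMM-scaled means of the summed counts. Summed CPM of cell type markers are scaled to the UMIs of the library only, without TMM. The TMM factors ran from 0.839 (flank naive library 2) to 1.16 (flank tumour-draining library 1), so marker sums and gene CPM are not on 1 scale. Lists of genes were fixed before the data were examined, as were the comparisons, the filters and the alternatives other than those named below: Th1, IFN-gamma response, type I interferon response, Treg core, effector Treg, resting or central T cell, ST2 tissue Treg, Th17, follicular, homing receptors, TCR signalling, dissociation stress, cell cycle, cytotoxic, interleukin 2 and STAT5, inhibitory receptors, glycolysis and cholesterol synthesis. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over lists within a comparison. An estimated correlation and the self-contained fry were alternatives. At the preset correlation, other splits of the tumour-bearing mice gave a median of 6 called lists. Calls at that setting alone are therefore weak evidence. Some genes are in several lists (Icos in effector, follicular and interleukin 2, Gzmb in effector and cytotoxic), so lists are not independent.

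Genes were named by a rule fixed beforehand: per comparison the 10 rising and 10 falling genes with the largest change among those past the threshold, with at least 20 CPM in the higher group and libraries that did not overlap (the last not for the difference of tumour effects), leaving out variable segments of receptors, mitochondrial, ribosomal, Gm-numbered and Rik genes. Up to 4 members per list with the smallest p, and Foxp3, Cxcr3, Tbx21, Icos, Klrg1, Ctla4 and Il2ra (in cocultures Gzmb, Ifng, Il2ra, Prf1, Tnf, Cd69 and Foxp3) were added. Ifng was below the count filter in the cocultures. The text gives a part of the named genes, and some items are not reported here. Gene positions were taken for 234 of 238 named genes from a RefSeq table of the same assembly. Where a group had 0 counts of a gene, its fold was bounded with 3 counts over the group, and with 1 to 3 counts the ratio is given with a 95% counting interval. Both cover counting error only.

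Shares of cells with a UMI were taken after thinning every cell to 1000 UMIs and compared between mice with exact two-sided permutation tests in scipy 1.17.1. TCR beta chains were joined to cells by the cell barcode of 12 bases, since the table names no library, and 27.0% of 4397037 sequences found a lymph node cell. Of 4729 coculture barcodes 3.83% were found, which measures chance matches. A clonotype was a V gene, a J gene and a junction less its last 6 bases, and the share of cells in clonotypes of at least 2 cells was averaged over 1000 draws of equal cell numbers. Calls with at least 10 reads and amino acid junctions were alternatives. The fits were tested on simulated counts with genes changed by known folds. These counts were drawn from each fit's own means and dispersions. They show recovery under that model, and say nothing of false calls between mice or pools. For lung against flank tumour-draining nodes 93.9% of genes changed 4-fold were recovered and 4.58% of calls were false. The false share was 7.19% for naive nodes and 8.84% for the flank tumour. For the difference of tumour effects 56.1% of genes changed 2-fold and 87.7% of genes changed 4-fold were recovered and 8.18% of calls were false. For the cocultures 59.7 and 87.5% were recovered. Alternatives were the DESeq2 1.42.0 size factors and Wald test, no filter on counts, all barcodes, cells with a Foxp3 UMI, cocultures without cells holding a Foxp3 or Cd4 UMI, cells without Scrublet's calls, equal cells per library (260 in lymph nodes, 638 in cocultures), thinned cells, the replicate number as a block, only the groups compared, limma-voom per mouse and library, and leaving out each library. Chosen after the data were seen were the fits per mouse, leaving out clusters in which at least 40% of cells had a Mki67 UMI, the coculture without the cluster led by Lyz2 and S100a9 or with only cells holding a Mki67 UMI, unthinned shares and the TCR join. The limma-voom fit blocked on the library and not on the mouse, so a mouse entered once per library as if independent. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.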

Results

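Regulatory T cells (Tregs) are CD4 T cells that restrain immune responses and depend on the transcription factor Foxp3. They were sorted from lymph nodes of C57BL/6J mice and profiled by Seq-Well, a microwell method of single-cell RNA sequencing that counts transcripts by unique molecular identifiers (UMIs). The mediastinal node, which drains the lung, came from mice with lung tumours and from naive mice. The inguinal node, which drains the flank, came from mice with flank tumours and from naive mice. Each of these 4 groups had 2 libraries. A second experiment sequenced CD8+ OT-I T cells, which carry a receptor for a peptide of ovalbumin, after 3 days of culture with type 1 dendritic cells (DC1) from the draining mediastinal node of tumour-bearing mice. It had 2 libraries without Tregs and 1 library with Tregs of that node, at 1 Treg to 8 OT-I cells.

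The lung tumour-draining libraries held 2505 and 2450 passing cells with a median of 2846 and 2514 UMIs per cell and 9567265 and 8189508 UMIs in all. The flank tumour-draining libraries held 806 and 995 cells with medians of 2501 and 2361 and totals of 2670561 and 2987795. The lung naive libraries were unequal, with 3094 and 260 cells, medians of 2943 and 2497 and totals of 10960596 and 753766. The flank naive libraries held 2749 and 3282 cells with medians of 4169 and 4406 and totals of 14451415 and 17237116. The cocultures without Tregs held 2057 and 1940 cells with medians of 7413 and 5449.5 and totals of 18608250 and 13235377, and the coculture with Tregs held 638 cells with a median of 4690.5 and a total of 4501570. In the tumour-draining groups, 94.7 to 99.2% of cells were assigned to an antibody hashtag, and hashtags labelled mice per the series' design text. Each hashtag was taken as 1 mouse. The same 5 hashtags occurred in both libraries of a group. Of cell pairs with a TCR clonotype in common across them, 68.1% (lung) and 95.4% (flank) carried the same hashtag. Of all cell pairs, 23.97 and 24.98% did (at least 10 reads behind a TCR call). These values argue that both libraries of a group hold cells of the same pooled mice. SDs and p-values over such libraries would measure only technical spread. For the naive and coculture libraries nothing used here says that they came from separate animals or wells.

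The first comparison asked how Tregs of the node draining a lung tumour differ from those of the node draining a flank tumour, which bears on the study's question about tissue-specific interferon-gamma (IFN-gamma). Tregs of the lung tumour-draining node had less RNA of the effector Treg list and more of the resting T cell list. Of 29 tested effector Treg genes, 12 were lower, 1 was higher and 16 did not pass the test (19 lower and 2 higher adjusted over the list alone). Icos, a costimulatory receptor encoded on chromosome 1 (60960773 to 61000322, mm10), stood at 175 ± 2.48 CPM (UMI counts scaled to a common library total) against 623 ± 18.3 (SD, n = 2 libraries each). Its log2 fold change was -1.83 with a standard error of 0.141. Gzmb, the protease granzyme B, stood at 41.6 ± 1.13 against 136 ± 0.549 CPM, and Lag3, an inhibitory receptor, at 19.9 ± 1.05 against 64.5 ± 13.6 CPM. Of 18 tested resting or central T cell genes, 11 were higher, 0 were lower and 7 did not pass (14 higher and 1 lower adjusted over the list alone). Igfbp4 stood at 76.8 ± 1.86 against 30.3 ± 8.46 CPM. Bcl2, an inhibitor of cell death, stood at 174 ± 15.5 against 72.1 ± 17.3 CPM, and Bach2, a repressor of effector genes, had a log2 fold change of 1.07. Camera placed the effector list lower (median log2 fold change -0.56, adjusted p = 1.46e-18) and the resting list higher (median 0.63, adjusted p = 1.74e-13). Over libraries both calls were lost, at an adjusted p = 0.0814 with an estimated correlation for each list. The summed B cell markers, without TMM scaling, moved with the effector list, at 353 and 422 CPM in the lung libraries against 596 and 553 CPM in the flank libraries. So did the CD8 T cell markers, which share Gzmb with that list, at 110 and 121 against 205 and 213 CPM. Gzmb alone, at 41.6 against 136 CPM, differed by about as much as that sum. The sum therefore gives no sign of CD8 T cells apart from Gzmb. The B cell gene Cd79a did not move with the effector list. Without thinning it was found in 0.0803% of cells of the lung and 0% of the flank libraries on average.

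Some genes of the IFN-gamma response and homing lists differed between the same nodes. Of 37 tested IFN-gamma response genes, 12 were higher in the lung tumour-draining node, 1 was lower and 24 did not pass (20 higher and 1 lower adjusted over the list alone; camera adjusted p = 4.31e-09, adjusted p = 0.145 with an estimated correlation). Gbp10, an interferon-induced GTPase on chromosome 5 (105215699 to 105239533), stood at 46.8 ± 3.68 against 19.96 ± 5.80 CPM, and the transcription factor Irf1 at 250 ± 28.2 against 146 ± 25.5 CPM. Ly6a was the lower member, at 187 ± 11.7 against 324 ± 22.4 CPM. The summed myeloid markers stood at 362 and 328 CPM in the lung libraries and at 291 and 309 CPM in the flank libraries. The cluster with the most cells was led by the interferon-induced Ifit3, Ifit1 and Gbp10 in both lung libraries and by Rrm2, Lgals3 and Uhrf1 in both flank libraries. Among 24 homing receptor genes, 3 were higher, 8 were lower and 13 did not pass (6 higher and 9 lower adjusted over the list alone). Itga4, the alpha chain of very late antigen 4 on chromosome 2 (79255426 to 79333114), had the largest rise among genes that met the naming rule, at 339 ± 4.65 against 50.9 ± 8.75 CPM (log2 fold change 2.73, standard error 0.157, adjusted p = 8.45e-09). Ccr10, a receptor for skin chemokines, stood at 0.755 ± 0.208 against 28.2 ± 4.12 CPM (log2 fold change -5.20). The glycosyltransferases Gcnt1 and Fut7, which build selectin ligands, had log2 fold changes of -3.51 and -2.44. The homing list's median of 0.08 and mean of -0.37 differed in sign, and camera called it lower (adjusted p = 0.000452, adjusted p = 0.0814 with an estimated correlation).

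Some genes of the cell cycle, glycolysis and cholesterol synthesis lists were lower in the lung tumour-draining node. Of 31 cell cycle genes, 12 were lower and 19 did not pass (28 lower adjusted over the list alone). Of 20 glycolysis genes 7 were lower and 13 did not pass (12 over the list alone). Of 17 cholesterol synthesis genes 5 were lower and 12 did not pass (8 over the list alone). Aurkb, a mitotic kinase, had a log2 fold change of -0.80, Tyms, which makes thymidylate, of -0.71. The glycolytic enzyme Pgk1 stood at -0.98, the lactate transporter Slc16a3 at -1.13 and Fdps, of the mevalonate pathway, at -0.77. Camera called these 3 lists lower (adjusted p = 3.00e-14, 5.29e-09 and 1.49e-05), with adjusted p = 0.149, 0.0814 and 0.0869 with an estimated correlation. Of 13 genes of ST2-expressing tissue Tregs, 5 were lower and 1 was higher (10 and 1 adjusted over the list alone; adjusted p = 1.35e-07, adjusted p = 0.0869 with an estimated correlation), among them the chemokine receptor Ccr8 at 11.7 ± 1.87 against 22.6 ± 1.70 CPM. Foxp3 itself stood at 290 ± 3.60 against 272 ± 19.2 CPM (log2 fold change 0.09, edgeR adjusted p = 0.757). The Th1 receptor Cxcr3 stood at 56.8 ± 9.76 against 56.8 ± 2.56 CPM and the Th1 factor Tbx21 at 13.95 ± 0.749 against 12.5 ± 2.53 CPM, and neither passed. Outside clusters rich in Mki67, a choice made after the data were seen, Cxcr3 was lower in the lung tumour-draining node by a log2 fold change of -1.32, and this passed the test over libraries and over mice. The Th1 list had 7 lower members of 16, among them Il12rb1 (8 lower and 3 higher adjusted over the list alone; camera adjusted p = 0.00096, adjusted p = 0.0814 with an estimated correlation). Of 17 cytotoxic genes 6 were lower (7 lower and 3 higher adjusted over the list alone; adjusted p = 0.000132, adjusted p = 0.0814 with an estimated correlation). Type I interferon response genes had 5 higher and 1 lower of 30 (13 and 4 adjusted over the list alone; adjusted p = 0.0688).

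Dissociation stress genes, by which handling of cells is often read, had 3 higher members of 18 (3 adjusted over the list alone; adjusted p = 0.0028, adjusted p = 0.0814 with an estimated correlation; median 0.17, mean 0.82), with Hspa1a at 99 counts against 0, at least 10.53-fold higher by a floor of 3 counts over the group. Median mitochondrial shares were 8.23 and 6.70% in the lung libraries against 4.54 and 5.94% in the flank libraries. Of 8 Th17 genes 3 were lower (4 lower and 1 higher adjusted over the list alone; adjusted p = 0.0132, adjusted p = 0.155 with an estimated correlation). Of 8 follicular genes 2 were lower and 1 was higher (3 and 1 adjusted over the list alone; adjusted p = 0.0132, adjusted p = 0.0978 with an estimated correlation). Of 18 inhibitory receptor genes 4 were lower and 2 higher (5 and 4 adjusted over the list alone; adjusted p = 0.0292, adjusted p = 0.149 with an estimated correlation), with a median of 0.04 above 0 and a mean of -0.16 below it. The Treg core list (5 higher and 3 lower of 17, 6 and 4 adjusted over the list alone), the TCR signalling list (1 lower of 16, 1 adjusted over the list alone) and the interleukin 2 list (3 higher and 3 lower of 18, 5 and 6 adjusted over the list alone) were not called (camera adjusted p = 0.183, 0.750 and 0.480).

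In this comparison 856 of 11134 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 458 higher and 398 lower in the lung tumour-draining node, of which 143 and 127 changed over 2-fold. On simulated counts for this comparison the fit recovered 64.6% of genes changed 2-fold. With UMIs summed per mouse by hashtag, 5 mice against 5, 2696 of 8676 tested genes passed, 1287 higher and 1409 lower. In that fit the effector, resting, ST2, cell cycle and glycolysis lists passed with an estimated correlation (adjusted p = 0.0355, 0.00353, 0.0372, 0.0355 and 0.00353), and the IFN-gamma list, with 25 higher and 1 lower member, did not (adjusted p = 0.327 with an estimated correlation). At the preset correlation the homing, cytotoxic and inhibitory receptor lists were not called over mice (adjusted p = 0.246, 0.152 and 0.418). Per mouse, Itga4 stood at 362 ± 37.9 against 52.2 ± 6.68 CPM (SD, n = 5 mice each). Leaving out a single library moved the count of 856 to 147 without lung tumour-draining library 1, 110 without flank tumour-draining library 1, 464 without flank tumour-draining library 2, 1409 without lung naive library 1 and 1415 without lung naive library 2. Without clusters rich in Mki67, chosen after the data were seen, 394 genes passed over libraries, 131 higher and 263 lower. The balance of higher and lower also turned without flank tumour-draining library 1, at 39 and 71, and with every cell thinned to 1000 UMIs, at 358 and 436. It turned as well with DESeq2's size factors, at 418 and 457, with only the groups compared in the fit, at 778 and 816, and per mouse and library with limma-voom, at 959 and 1105.

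**Figure D1:**
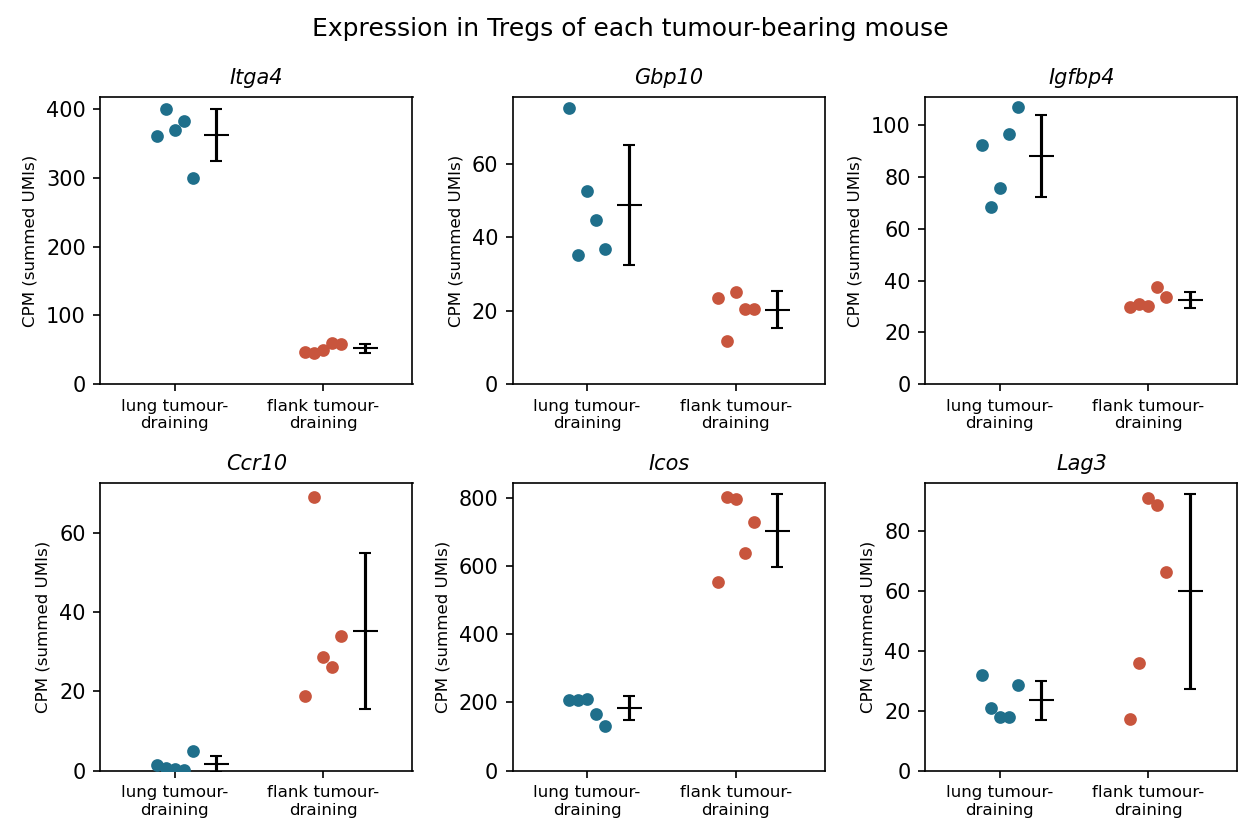
Expression of 6 genes in Tregs of each tumour-bearing mouse, in CPM of UMIs summed over both libraries by hashtag. Points are mice, 5 per group, and the bar beside them is the mean with its SD; Itga4 averaged 362 CPM in the lung group and 52.2 CPM in the flank group.

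The share of cells with a UMI of a gene was compared after thinning every cell to 1000 UMIs, a depth that every passing cell reached, so that 0 cells were left out. Icos was found in 11.2 ± 0.747% of Tregs of the lung tumour-draining node and 33.5 ± 3.01% of the flank tumour-draining node (SD, n = 2 libraries), against 6.65 ± 1.25% in lung naive and 7.99 ± 1.30% in flank naive nodes. Without thinning these shares were 24.99, 53.5, 14.6 and 22.7%. Mki67, a marker of cycling cells, was found in 17.4 ± 3.90% and 37.8 ± 6.78% of cells of the tumour-draining nodes and in 9.77 ± 6.31% and 6.07 ± 0.202% of the naive nodes (24.6, 49.1, 13.7 and 11.9% without thinning). Foxp3 was found in 27.3 ± 1.51% and 27.4 ± 2.13% of cells of the tumour-draining nodes (53.3 and 51.3% without thinning), a share set by depth as well as by the sort. Per mouse, Icos averaged 10.6 ± 2.10% in the lung group and 35.4 ± 8.56% in the flank group, and Mki67 16.5 ± 3.35% and 40.8 ± 7.47% (n = 5 mice each; exact permutation test, two-sided, p = 0.00794 for each, adjusted p = 0.0357 over 9 genes). Cxcr3 averaged 3.38 ± 1.59% and 5.89 ± 1.54% (exact p = 0.0476, adjusted p = 0.0857), with 60.1 ± 17.9 against 69.6 ± 17.2 CPM per mouse (edgeR adjusted p = 0.875). The background genes Lyz2 and Cd79a, of myeloid and B cells, were found in 0 cells of these mice at this depth. Over libraries, 2 against 2 cannot give a two-sided exact p below 0.33. Groups did not overlap in 21 of 28 comparisons, and in 19 with cells thinned to 500 UMIs. Chance gives 33.3% only for independent libraries, which the shared hashtags speak against for the tumour-draining groups.

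**Figure D2:**
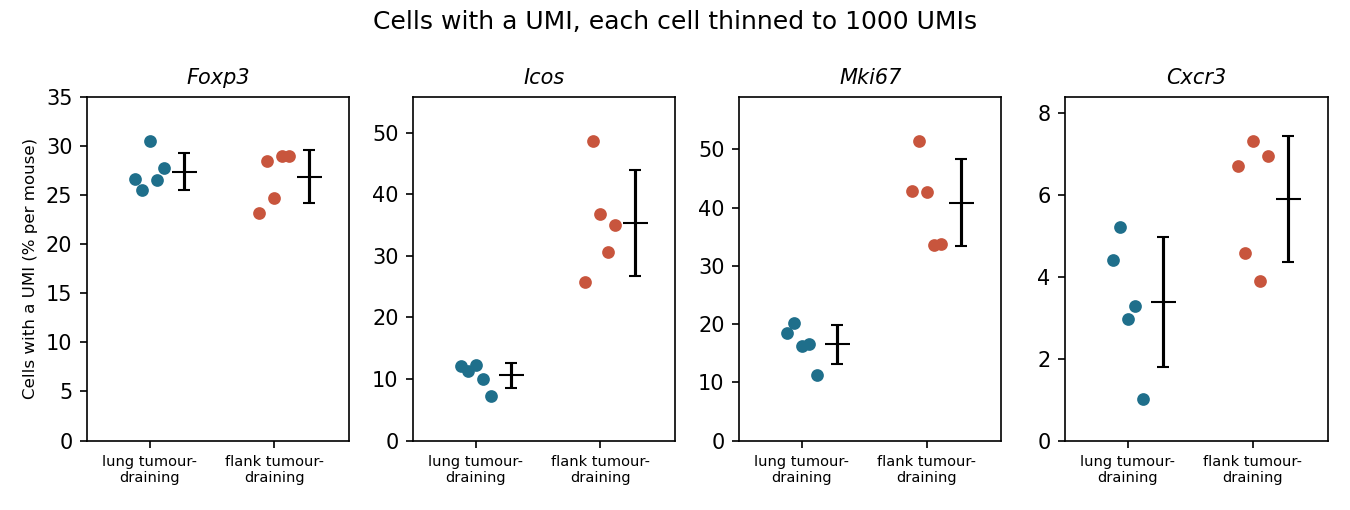
Share of Tregs with at least 1 UMI of Foxp3, Icos, Mki67 and Cxcr3 in each tumour-bearing mouse, in percent of cells thinned to 1000 UMIs. Points are mice, 5 per group, and the bar beside them is the mean with its SD; Icos averaged 10.6% in the lung group and 35.4% in the flank group.

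The naive nodes were compared to see how Tregs of the lung-draining and flank-draining nodes differ without a tumour. Here 68 of 11134 genes passed, 37 higher and 31 lower in the lung-draining node. Rgs16, a regulator of G protein signalling, was higher, at 62.6 ± 2.01 against 14.9 ± 1.92 CPM (SD, n = 2 libraries each; log2 fold change 2.09, standard error 0.147). So were the follicular homing receptor Cxcr5 at 36.2 ± 3.24 against 13.2 ± 0.513 CPM and the calcium channel Ryr2 at 30.9 ± 2.59 against 5.66 ± 1.11 CPM. Itga4 was higher by a log2 fold change of 0.69, at 285 ± 28.3 against 179 ± 7.63 CPM. Icos (log2 fold change -0.79), S100a4 (-1.23) and Klrg1, a receptor of differentiated T cells (-0.98), were lower. Ccr10 had 0 counts against 209, at least 25.9-fold lower by a floor of 3 counts over the group. Gzmb had 3 counts in the lung naive group against 114 in the flank naive group, a ratio of 14.1 with a counting interval of 4.72 to 69.6.

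By list, 6 of 18 were called between the naive nodes, none of them with an estimated correlation. None of 37 IFN-gamma response genes passed, nor did any adjusted over the list alone (median log2 fold change -0.03, camera adjusted p = 0.183). Type I interferon response genes were placed lower in the lung-draining node (median -0.34, adjusted p = 1.13e-07, adjusted p = 0.538 with an estimated correlation), with Ifit3 the member of 30 that passed (4 adjusted over the list alone). Of 29 effector Treg genes, 4 were lower and 1 was higher (9 and 3 adjusted over the list alone; adjusted p = 0.00245, adjusted p = 0.538 with an estimated correlation). Dissociation stress genes were placed higher (2 of 18 passed, Hspa1a and Hspa1b, and 5 adjusted over the list alone; adjusted p = 6.67e-07, adjusted p = 0.111 with an estimated correlation). The resting, TCR signalling and cholesterol lists were called lower, higher and higher (adjusted p = 0.000831, 0.0036 and 0.0041) though none of their members passed over all genes. Adjusted over the list alone, 3 resting and 2 TCR signalling genes did. Each of these 3 lists was at adjusted p = 0.538 with an estimated correlation. Cxcr3 stood at 19.9 ± 4.07 against 10.2 ± 0.651 CPM (adjusted p = 0.074), Tbx21 at 4.53 ± 1.65 against 1.37 ± 0.0201 CPM (adjusted p = 0.109) and Foxp3 at 298 ± 59.2 against 393 ± 4.63 CPM (adjusted p = 0.512). Lung naive library 2 held 260 cells, and the count of 68 became 110 without it, 40 without flank naive library 1 and 83 without lung naive library 1, of which only 10 were among the 68. The balance of higher and lower turned without flank naive library 2, at 22 and 38, with no filter on counts, at 97 and 102, with the replicate block, at 36 and 40, and in cells with a Foxp3 UMI, at 36 and 37.

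To see what a tumour changes in each draining node, tumour-bearing and naive mice were compared within a site. Hashtag counts are given only for the tumour-draining libraries, so labelling, pool and handling cannot be told apart from the tumour here. In the lung-draining node, cell cycle, interferon and Th1 genes rose together. Of 31 cell cycle genes 26 rose, of 37 IFN-gamma response genes 21 rose, of 30 type I interferon response genes 20 rose and of 16 Th1 genes 9 rose, with 0 falling in these lists (30, 25, 26 and 11 adjusted over each list alone). The cyclin Ccnb1 stood at 34.7 ± 6.79 against 5.31 ± 3.48 CPM (SD, n = 2 libraries each), Gbp10 at 46.8 ± 3.68 against 13.4 ± 0.793 CPM and the interferon-induced Isg15 at 56.0 ± 6.83 against 20.8 ± 1.18 CPM. Tbx21 stood at 13.95 ± 0.749 against 4.53 ± 1.65 and Cxcr3 at 56.8 ± 9.76 against 19.9 ± 4.07 CPM (log2 fold change 1.68, standard error 0.178). Of 29 effector Treg genes 14 rose and 1 fell (17 and 1 adjusted over the list alone), with Lgals3, a galectin, at 87.2 ± 20.7 against 7.80 ± 5.08 CPM. Gzmb had 781 counts against 3, a ratio of 171 with a counting interval of 58.3 to 832. Camera called these 5 lists higher (adjusted p = 4.09e-38, 1.79e-26, 4.58e-19, 3.05e-09 and 5.90e-19), each with adjusted p = 0.0926 with an estimated correlation.

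In the same node the glycolysis and cholesterol lists each had 7 members that rose (8 and 11 adjusted over each list alone; adjusted p = 7.26e-05 and 1.20e-07, adjusted p = 0.133 with an estimated correlation for each), and the cytotoxic list had 5 of 17 (6 adjusted over the list alone; adjusted p = 5.57e-06, adjusted p = 0.0926 with an estimated correlation). Dissociation stress genes had 5 that fell and 2 that rose of 18 (7 and 2 adjusted over the list alone; adjusted p = 0.00171, adjusted p = 0.0926 with an estimated correlation), among them the immediate early genes Fos at -1.29 and Dusp1 at -1.25 on the log2 scale. Resting genes had 3 that fell of 18 (3 adjusted over the list alone; adjusted p = 0.000458, adjusted p = 0.309 with an estimated correlation) and TCR signalling genes 3 of 16 (4 adjusted over the list alone; adjusted p = 0.00326, adjusted p = 0.309 with an estimated correlation). Foxp3 had a log2 fold change of -0.07 (edgeR adjusted p = 0.834). The summed B cell markers moved with the lists that rose, at 353 and 422 CPM in the tumour-draining against 249 and 197 CPM in the naive libraries. Without thinning, the B cell gene Cd79a was found in 0.0803 ± 0.0558% of tumour-draining and 0.0485 ± 0.0686% of naive cells (SD, n = 2 libraries each). In all 941 genes passed, 672 higher and 269 lower with the tumour, 363 and 66 of them over 2-fold. The count was 617 without lung tumour-draining library 1, 380 without lung tumour-draining library 2 and 65 without lung naive library 1, when only the small naive library of 260 cells remained. Without clusters rich in Mki67 it was 110, of which 81 were among the 941, and 111 of the 941 had the opposite sign.

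In the flank-draining node 4192 of 11134 genes passed, 2182 higher and 2010 lower with the tumour (835 and 697 over 2-fold). This count cannot be set against the 941 of the lung-draining node as a larger effect, since 1 lung naive library held only 260 cells. Effector, cell cycle and metabolic genes rose and resting genes fell. Of 29 effector Treg genes 26 rose and 2 fell (26 and 2 adjusted over the list alone), of 31 cell cycle genes 31 rose (31 over the list alone). Of 17 cholesterol synthesis genes 15 rose (15), of 20 glycolysis genes 15 rose (16). Of 16 Th1 genes 12 rose (12, with 2 falling) and of 18 resting genes 16 fell (16). Gzmb stood at 136 ± 0.549 against 4.32 ± 1.80 CPM (SD, n = 2 libraries each; log2 fold change 4.99, standard error 0.198) and Icos at 623 ± 18.3 against 154 ± 17.6 CPM. Lag3 stood at 64.5 ± 13.6 against 6.37 ± 1.16, Cxcr3 at 56.8 ± 2.56 against 10.2 ± 0.651 and Fdps at 84.5 ± 6.87 against 21.1 ± 0.0603 CPM. Igfbp4 fell from 157 ± 3.18 to 30.3 ± 8.46 CPM. Il7r, the receptor for interleukin 7, fell from 107 ± 7.86 to 29.2 ± 2.39 and Bcl2 from 246 ± 14.4 to 72.1 ± 17.3 CPM. Foxp3 fell from 393 ± 4.63 to 272 ± 19.2 CPM (log2 fold change -0.53, adjusted p = 0.00843), while its thinned share was 27.4 ± 0.559% in naive and 27.4 ± 2.13% in tumour-draining libraries.

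With an estimated correlation the Th1, cholesterol and cytotoxic lists (adjusted p = 0.0399 each) and glycolysis (adjusted p = 0.0434) passed in this node, and cell cycle and resting (adjusted p = 0.0649 each) and effector (adjusted p = 0.0613) did not. Camera's adjusted p was 4.30e-10 for Th1, 5.15e-13 for cholesterol, 3.05e-08 for cytotoxic, 3.05e-11 for glycolysis, 4.78e-38 for cell cycle, 1.05e-14 for resting and 1.26e-20 for effector genes. Of 17 cytotoxic genes 10 rose and 1 fell (10 and 2 adjusted over the list alone), and of 13 genes of ST2-expressing tissue Tregs 11 rose (11; adjusted p = 1.88e-05, adjusted p = 0.146 with an estimated correlation). Of 37 IFN-gamma response genes 15 rose and 2 fell (15 and 2 adjusted over the list alone), with a median of 0.25 (adjusted p = 0.0438, adjusted p = 0.560 with an estimated correlation), and of 30 type I genes 9 rose and 3 fell (9 and 3; adjusted p = 0.0531). Homing genes had 11 that rose and 7 that fell (11 and 7; adjusted p = 0.00485, adjusted p = 0.0721 with an estimated correlation) and follicular genes 4 and 1 (4 and 1; adjusted p = 0.0025, adjusted p = 0.0649 with an estimated correlation). The summed B cell markers again moved with the lists that rose, at 596 and 553 CPM against 224 and 212 CPM without TMM scaling. The TMM factors were 1.16 and 1.13 with and 0.886 and 0.839 without the tumour, so scaling would narrow this gap. The B cell gene Cd79a did not move with those lists. Without thinning it was found in 0% of tumour-draining and 0.131 ± 0.0306% of naive cells (SD, n = 2 libraries each). Dissociation stress genes had 10 that fell and 5 that rose of 18 (11 and 5 adjusted over the list alone; median -0.73, adjusted p = 0.0844). Median mitochondrial shares were 4.54 and 5.94% in the tumour-draining against 10.3 and 7.48% in the naive libraries. Leaving out flank tumour-draining library 1 moved the count of genes to 2387, and leaving out clusters rich in Mki67 moved it to 993, of which 909 were among the 4192 with the same sign. In that fit 201 of the 4192 had the opposite sign, 2 of them called.

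Whether the tumour changed Tregs differently in the nodes was tested as the difference of the tumour effects, lung minus flank. By list, 12 of 18 were called. Of 18 resting genes 7 had a higher tumour effect in the lung-draining node (12 adjusted over the list alone; median difference 0.72 on the log2 scale, adjusted p = 2.85e-17, adjusted p = 0.160 with an estimated correlation), with Il7r at 1.70, Igfbp4 at 1.56 and Bcl2 at 1.40. Of 30 type I interferon response genes 5 had a higher effect (14 adjusted over the list alone; median 0.58, adjusted p = 1.80e-08, adjusted p = 0.192 with an estimated correlation), with Ifit3 at 1.62. Of 37 IFN-gamma response genes only Tgtp2, at 1.27, passed (9 adjusted over the list alone; median 0.44, adjusted p = 1.12e-08, adjusted p = 0.192 with an estimated correlation). Of 20 glycolysis genes 4 had a lower effect (9 adjusted over the list alone; median -0.60, adjusted p = 3.90e-10, adjusted p = 0.136 with an estimated correlation), with Pgk1 at -1.38 and Slc16a3 at -1.27. Of 17 cholesterol genes 2 did, among them Fdps at -1.16 (7 adjusted over the list alone; adjusted p = 3.05e-08, adjusted p = 0.186 with an estimated correlation). Of 31 cell cycle genes only Mcm2 did, at -1.02 (15 adjusted over the list alone; adjusted p = 8.16e-12, adjusted p = 0.229 with an estimated correlation). Of 29 effector genes 5 had a lower and 1 a higher effect (10 and 2 adjusted over the list alone; median -0.34, adjusted p = 3.60e-06, adjusted p = 0.229 with an estimated correlation), with Lag3 at -3.00, Ccr2 at -1.91 and Icos at -1.04. Of 13 genes of ST2-expressing tissue Tregs 3 had a lower effect (6 adjusted over the list alone; median -0.88, adjusted p = 6.23e-07, adjusted p = 0.191 with an estimated correlation). The Th1, Th17, follicular and TCR signalling lists were also called lower (adjusted p = 0.00801, 0.0245, 0.0146 and 0.0375; adjusted p = 0.187, 0.240, 0.187 and 0.385 with an estimated correlation). Itga4 had the reverse difference, 2.04 with a standard error of 0.210 (adjusted p = 8.92e-05). Cxcr3 at -0.80 (adjusted p = 0.0997) and Tbx21 at -1.21 (adjusted p = 0.149) did not pass in edgeR's test.

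In all 211 of 11134 genes had a different tumour effect, 137 higher and 74 lower in the lung-draining node, 102 and 52 of them over 2-fold. Without clusters rich in Mki67, chosen after the data were seen, the balance turned, with 84 higher and 154 lower of 238, of which 114 were among the 211. The count of 211 rested on single libraries: it was 11 without lung tumour-draining library 1, 15 without flank tumour-draining library 1 (6 higher and 9 lower), 120 without flank tumour-draining library 2, 528 without lung naive library 1, 331 without lung naive library 2, 105 without flank naive library 1 and 55 without flank naive library 2. The nodes share no controls, and 587 genes rose with the tumour in both, where lists of these sizes drawn independently would share 132, while 212 fell in both (48.6 if independent). Opposite calls were made for 3 genes in each direction (121 and 52.7 if independent). Across the 11134 genes, which are not independent replicates, the log2 fold changes of both nodes had a Pearson correlation of 0.588.

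**Figure D3:**
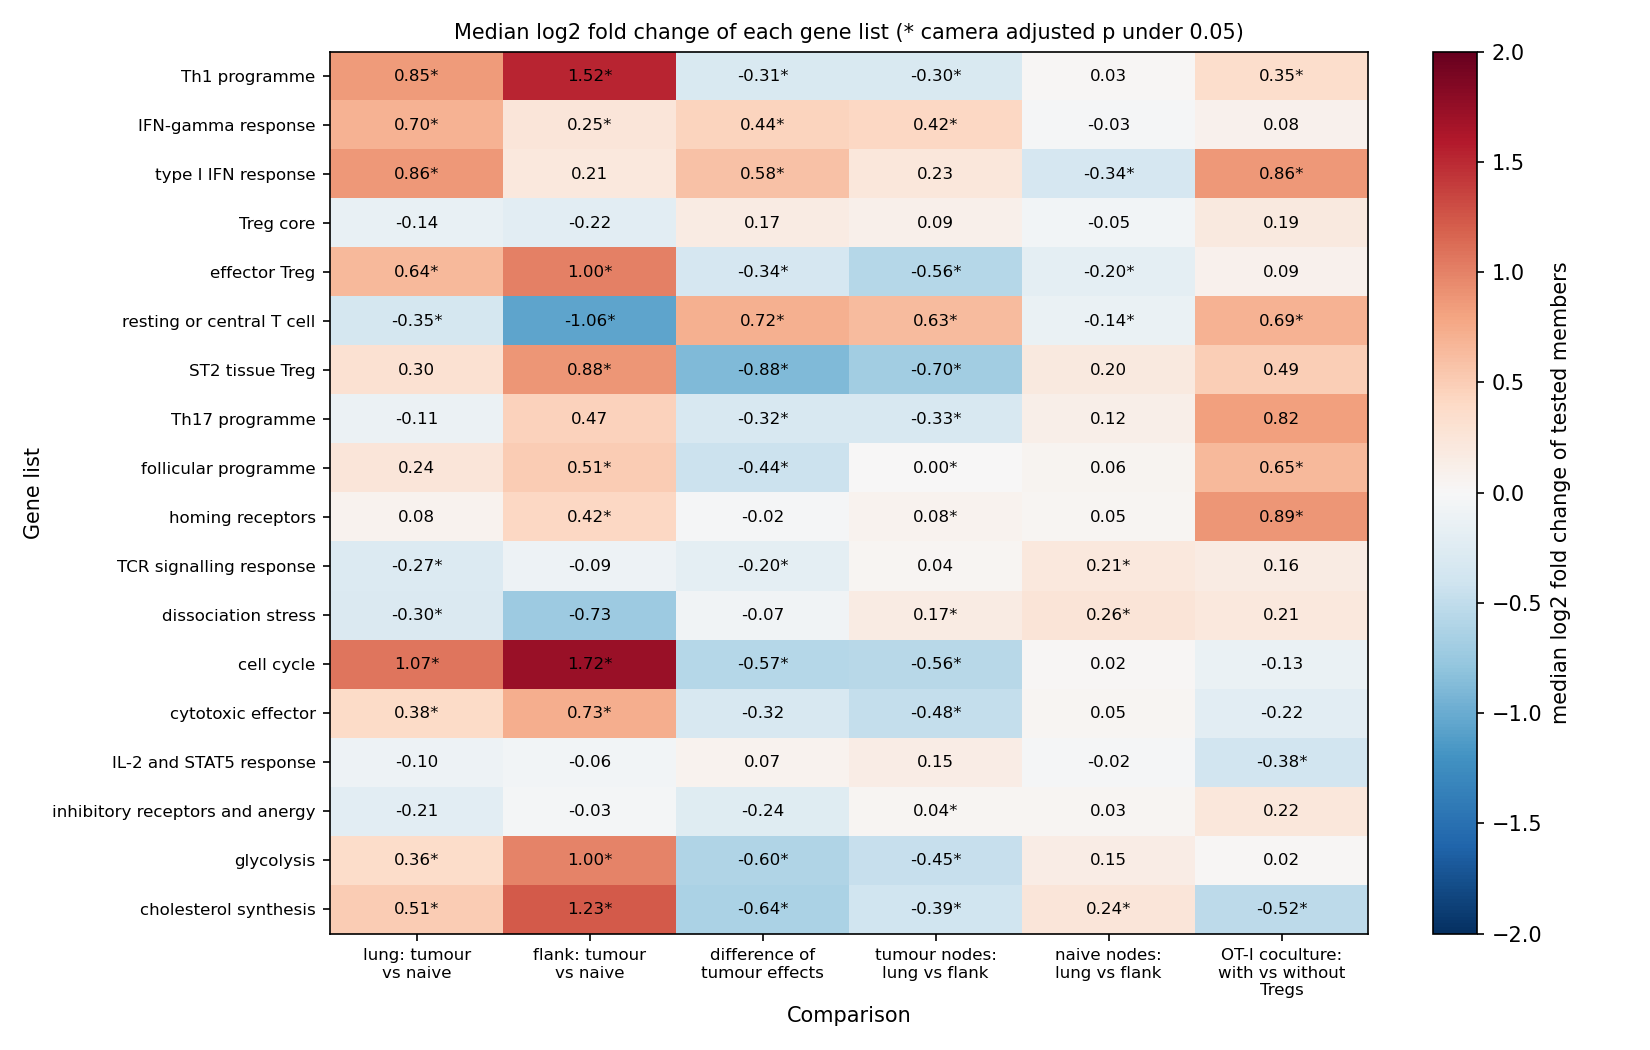
Median log2 fold change of the tested members of 18 gene lists (vertical axis) in 6 comparisons (horizontal axis), with the value printed in each field and a colour scale from blue (lower) to red (higher). An asterisk marks a camera adjusted p under 0.05 at the preset correlation, which most lists lost with an estimated correlation. The resting list stood at -1.06 in the flank-draining node with the tumour and at 0.72 in the difference of tumour effects.

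The coculture asked what Tregs change in OT-I cells while DC1 prime them. In the library with Tregs, OT-I cells had more RNA of the resting T cell and homing lists and less of Gzmb and other single genes. The test had 1 residual degree of freedom and took the single library with Tregs to vary like the pair without, so it compares these libraries. Gzmb stood at 285 CPM in the library with Tregs against 1222 ± 250 CPM without (SD, n = 2 libraries; log2 fold change -2.10, standard error 0.194, adjusted p = 2.43e-24). The serpin Serpine2 stood at 27.2 against 173 ± 60.1, the activation factor Irf4 at 34.5 against 113 ± 17.5 CPM. The interleukin 2 receptor chain Il2ra stood at 141 against 366 ± 92.3 and Myc, which drives growth, at 57.5 against 132 ± 10.02 CPM. S1pr1, of lymph node exit, stood at 199 against 39.1 ± 12.1 CPM. The transcription factor Klf2 stood at 113 against 45.3 ± 13.97 and Cd7 at 58.7 against 4.52 ± 1.51 CPM (log2 fold change 3.67). Of 18 resting genes 13 were higher and 1 was lower (15 and 2 adjusted over the list alone; adjusted p = 8.20e-15). Of 21 homing genes 14 were higher (14, with 1 lower; adjusted p = 3.51e-14) and of 24 type I interferon response genes 12 were higher and 1 was lower (14 and 1; adjusted p = 1.38e-07), among them Irf7. Each of these calls was lost, at adjusted p = 0.590 with an estimated correlation. Of 17 cholesterol genes 8 were lower (13 adjusted over the list alone; adjusted p = 9.72e-05), and of 18 interleukin 2 response genes 5 were lower and 3 higher (8 and 3; adjusted p = 0.00556), each with adjusted p = 0.597 with an estimated correlation. The Th1 and follicular lists were called higher, with 6 of 15 and 4 of 6 members higher and 2 and 0 lower (6 and 4 higher and 2 and 0 lower adjusted over each list alone; adjusted p = 0.0188 and 0.00213, adjusted p = 0.590 with an estimated correlation for each).

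Not every gene of cytotoxic function was lower with Tregs. Of 21 cytotoxic genes 5 were lower, 3 were higher and 13 did not pass (5 and 3 adjusted over the list alone; camera adjusted p = 0.145). Prf1, the pore-forming perforin, stood at 8.28 CPM with Tregs against 2.45 ± 0.708 CPM and the chemokine Ccl5 at 47.8 against 14.6 ± 1.17 CPM, both higher, while Gzmc stood at 9.70 against 26.2 ± 3.81 CPM. Tnf, with a log2 fold change of -0.49, and Cd69, with 0.35, did not pass. Of 31 cell cycle genes 3 were lower (3 adjusted over the list alone; camera adjusted p = 0.0944). The TCR signalling list, with 1 higher and 2 lower of 16 (2 and 2 adjusted over the list alone; adjusted p = 0.817), and the effector list, with 8 higher and 5 lower of 27 (10 and 5; adjusted p = 0.415), were not called. Foxp3 had 24 counts with Tregs against 0 without, at least 58.2-fold higher by a floor of 3 counts over the group. After thinning to 1000 UMIs, Gzmb was found in 10.2% of cells with Tregs and 40.3 ± 9.06% without (23.8 and 68.7% unthinned) and Mki67 in 34.8% and 45.5 ± 1.05% (54.2 and 82.8% unthinned), beside the myeloid gene Lyz2 in 5.96% and 3.99 ± 0.767% (31.7 and 22.7% unthinned).

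The summed myeloid markers moved with these lists, at 438 CPM with Tregs against 238 and 316 CPM without, as did the stromal markers, at 88.5 against 38.3 and 21.4 CPM, while the CD8 T cell markers, Gzmb among them, stood at 2332 against 2939 and 3455 CPM. In all 2170 of 11784 tested genes passed, 1126 higher and 1044 lower with Tregs, 418 and 255 of them over 2-fold. With every cell thinned to 1000 UMIs 1054 genes passed, 892 of them among the 2170, and 23 of the 2170 had the opposite sign after thinning. In cells with a Mki67 UMI, chosen after the data were seen, 1012 passed, 947 of them among the 2170. The cluster with the most cells of the library with Tregs was led by Pde2a, Cd7 and S1pr1, while that of the libraries without Tregs was led by Cdc6, Ung and Dtl in library 1 and by S100a9 and Lyz2 in library 2.

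**Figure D4:**
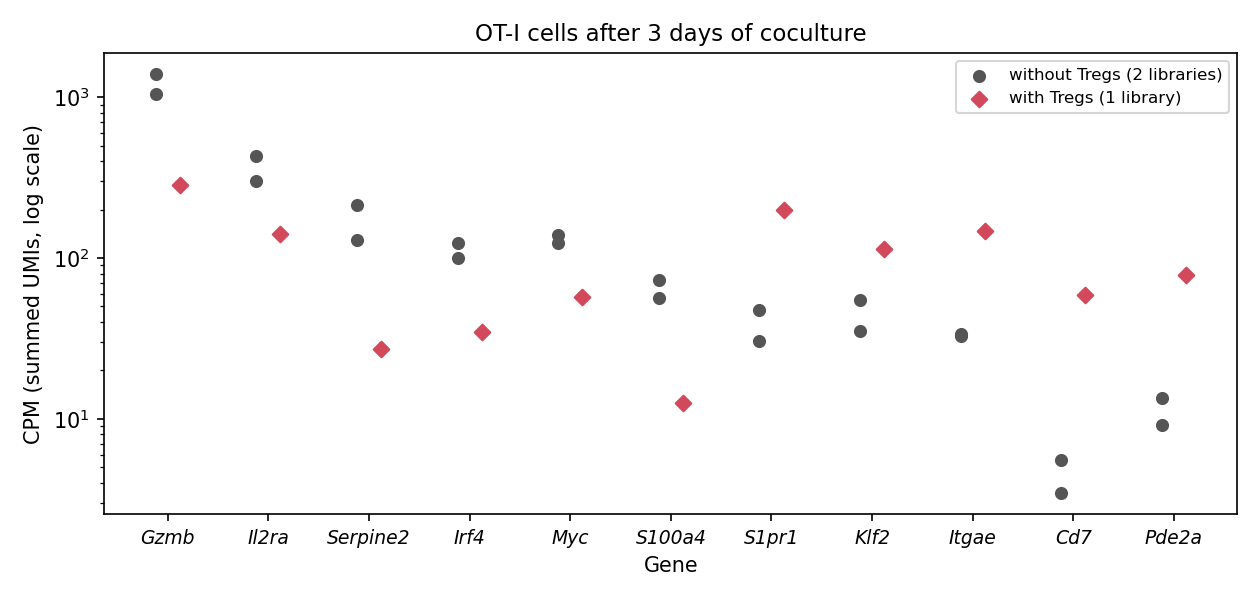
Expression of 11 genes in OT-I cells after 3 days of coculture, in CPM of summed UMIs on a log scale. Grey circles are the 2 libraries without Tregs and red diamonds the 1 library with Tregs; Gzmb stood at 285 CPM with Tregs and averaged 1222 CPM without.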

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

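Of the tests in this part, those of RNA from other cells, of the pool of each site, per mouse and of the TCR joined by barcode were chosen only after the result was seen.

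Tumour effects that differed between the lung-draining and flank-draining nodes, by the test of the difference itself, were found for 211 genes and 12 lists. On the log2 scale, lung minus flank, the difference was 2.04 for Itga4, 1.70 for Il7r, 1.62 for Ifit3, 1.56 for Igfbp4, 1.40 for Bcl2 and 1.27 for Tgtp2. It was -3.00 for Lag3, -1.91 for Ccr2, -1.38 for Pgk1, -1.27 for Slc16a3, -1.16 for Fdps, -1.04 for Icos and -1.02 for Mcm2. With an estimated correlation camera called 0 of the lists (4 at an unadjusted p under 0.05), and fry called 4. The count of 211 was 11 without lung tumour-draining library 1, 15 without flank tumour-draining library 1, 120 without flank tumour-draining library 2, 528 without lung naive library 1, 331 without lung naive library 2, 105 without flank naive library 1 and 55 without flank naive library 2.

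Single mice stood far from the other 4 of their group. At equal cells, 1 mouse of the lung group had 9.38% of cells in expanded clones, and with at least 10 reads behind a call 1 had 7.98%, both above the rest and the same mouse. For Ccr10, 1 lung mouse stood at 5.03 CPM. In all 3 of 56 groups of mice held such a value, where chance marks about 1 in 20. The groups counted were those of the TCR shares, of the shares of cells with Icos, Mki67 and Cxcr3, and of the CPM of genes named in the text for lung against flank tumour-draining nodes.

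IFN-gamma response genes were higher in Tregs of the lung than of the flank tumour-draining node, with a median log2 fold change of 0.42, and the cluster with the most cells of the lung libraries, unlike that of the flank libraries, was led by genes of interferon response (Ifit3, Ifit1 and Gbp10). Thinning every cell to 1000 UMIs kept 117% of the median (95% bootstrap interval over 36 members, taken as independent, 87.1 to 140). This argues against a median carried by the deeper cells. Thinning leaves the expected make-up of each cell as it is, so it could not test depth in other ways. RNA from other cells, which the sort for Tregs would remove, was weighed by summed CPM. The largest rise of a marker sum of another cell type, the myeloid one, was 45.0 CPM without TMM scaling. It was 2.35% of the rise of the summed list by 1915 TMM-scaled CPM. Abundant members weigh most in that list's sum. The values argue against other cells as the source of its rise, and do not settle it for members with few counts. The pool and its handling cannot be told apart from the site, since cells of multiple tumour-bearing mice were pooled before the sort. The site of the tumour stays open as an untested explanation. The IFN-gamma list's call was lost with an estimated correlation (adjusted p = 0.145 over libraries, 0.327 over mice). Ifit3 and Ifit1 belong to the type I interferon list, so the cluster does not tell the responses apart. The type I list had a median of 0.23 here and was not called (camera adjusted p = 0.0688). In the difference of tumour effects its median was 0.58, against 0.44 for the IFN-gamma list. Between the naive nodes the medians were -0.34 for the type I and -0.03 for the IFN-gamma list. The 0.58 thus rests in part on the naive nodes, where lung naive library 2 held 260 cells. Which interferon lies behind these genes was not tested.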

How the results depend on the processing

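The fits per mouse and those without clusters rich in Mki67 were chosen only after the results were seen. So were the coculture without the cluster led by Lyz2 and S100a9, that of only cells with a Mki67 UMI, and the unthinned shares. Other alternatives were set before. Where no reason is given, the cause was not tested. The limma-voom fit took the values of a mouse in each library as independent. For lung against flank tumour-draining nodes the 856 genes became 1319 with no filter on counts, 110 with equal cells per library, 394 without clusters rich in Mki67, 317 with DESeq2, 1594 with only the groups compared, 2064 per mouse and library with limma-voom, 2696 per mouse with edgeR and 2159 per mouse with DESeq2. For naive nodes the 68 genes became 199 with no filter, 14 with equal cells, 22 with thinned cells, 31 with DESeq2 and 45 with only the groups compared. For the lung tumour the 941 became 242 with equal cells, 170 thinned, 110 without clusters rich in Mki67 and 387 with DESeq2. For the flank tumour the 4192 became 1750, 2282, 993 and 2664 in the same order. The 211 genes with different tumour effects became 593 with no filter, 128 in cells with a Foxp3 UMI, 34 with equal cells and 85 with DESeq2. The coculture's 2170 became 684 with DESeq2, 1054 thinned and 1012 in cells with a Mki67 UMI. Equal cells, thinning and leaving out clusters each take counts away, by construction. The minimum of 500 genes and the step that leaves out clusters removed no cell, so these alternatives tested nothing.

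Leaving out 1 library, with a lone library taken to vary like the other groups, gave 110 to 1415 genes for lung against flank tumour-draining nodes, 40 to 110 for naive nodes, 65 to 1349 for the lung tumour, 2387 to 4731 for the flank tumour and 11 to 528 for the difference. The lists called were 13 to 15, 5 to 8, 7 to 12, 10 to 13 and 7 to 13. Leaving out 1 mouse gave 2217 to 2696 genes and 8 to 11 lists. The detection shares gave 21 to 26 comparisons without overlap. Leaving out a library cannot make separate groups overlap, so this count could not fall below the 21 of all libraries and tests nothing. In cocultures, leaving out a library left 1 against 1, which allows no test.

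With an estimated correlation, camera called 0 lists for lung against flank tumour-draining nodes (9 at an unadjusted p under 0.05; fry 12), 0 for naive nodes (1; fry 0, with 2 unadjusted), 0 for the lung tumour (7; fry 4), 4 for the flank tumour (fry 13), 0 for the difference (4; fry 4) and 0 for cocultures (0; fry 0, with 3 unadjusted). Without clusters rich in Mki67 the flank tumour had 17 lists. With the replicate number as a block (replicate block) the gene counts were 746, 76, 757, 3945 and 146. The numbers share only a number, with correlations of replicate differences between groups from -0.0958 to 0.142.

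Cxcr3 between the tumour-draining nodes went from near 0 to a called log2 fold change of -1.32 without clusters rich in Mki67, per library and per mouse. The alternatives that tested nothing or allowed no test were left out of the next counts. Of values of named genes, 1449 kept their call or its absence, 145 lost the call, 5 gained it and 2 reversed, both Cxcr3. A change of sign was counted as reversed only where a fit called the gene. Of list results 1033 were the same, 126 lost the call and 45 gained it.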

Other observations

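In this part the TCR join by barcode, the comparison of expanded with single clones, the test of added Tregs, the coculture's test of depth and the splits of mice were chosen only after the results were seen; the tests of doubly counted cells and of depth for expanded clones were set before.

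Clonally expanded Tregs, those that share a TCR beta chain with another cell, were more common with a tumour in both libraries of each site. Here 2 libraries against 2 cannot pass an exact test. The share at equal cells also depends on how many mice a library mixes. That number is not known for the naive libraries, so it cannot be told apart from the tumour. At 256 cells per library they made up 8.57 and 5.68% of cells of the lung tumour-draining node and 11.6 and 6.66% of the flank tumour-draining node, against 3.37 and 2.73% in lung naive and 1.09 and 0.940% in flank naive nodes. With at least 10 reads behind a call the means were 3.63, 7.85, 0.5258 and 0.144% in this order. Without flank tumour-draining library 1 the difference between the tumour-draining nodes changed sign, from -2.01 to 0.467 points. Per mouse, at 103 cells and at least 10 reads behind a call, the share was 3.84 ± 2.41% in the lung group and 10.98 ± 2.62% in the flank group (SD, n = 5 mice each; exact permutation test, two-sided, p = 0.00794). With no minimum of reads, at 106 cells, it was 4.98 ± 2.55% and 10.6 ± 2.77% (exact p = 0.0317), and this p rose to 0.0635 without any 1 of the flank mice with hashtags 2 and 3 or the lung mice with hashtags 6 to 9. Of pairs of cells with a clone in common across the 2 libraries of a group, 68.1% in the lung and 95.4% in the flank group carried the same hashtag at that minimum of 10 reads, and 41.6 and 81.6% with no minimum. Of all pairs of cells, 23.97 and 24.98% did.

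Of the genes tested, Mki67, Icos and Cxcr3 were found more often in expanded than in single-clone cells of the same mouse. With at least 10 reads behind a call and after thinning to 1000 UMIs, Mki67 was found in 61.0 ± 10.6% of expanded and 25.9 ± 13.05% of single-clone cells, Icos in 50.2 ± 22.8% and 19.8 ± 12.4%, and Cxcr3 in 14.8 ± 5.83% and 3.68 ± 1.98% (SD, n = 10 mice). Each was higher in 10 of 10 mice (exact sign-flip permutation p = 0.00195, the smallest these mice can give, adjusted p = 0.00391). Klrg1 was found in 3.93 ± 2.91% and 1.91 ± 1.90%, higher in 6 of 10 mice (permutation p = 0.0566, adjusted p = 0.0850), and the background gene Lyz2 in 0 cells. Foxp3 was found in 25.97 ± 7.18% and 26.9 ± 2.62% (permutation p = 0.746). Within the lung group its share was lower in expanded cells of 5 of 5 mice, at 22.2 ± 2.41% and 27.6 ± 2.20% (exact p = 0.0625, the smallest 5 mice can give). Within the flank group it was 29.8 ± 8.60% and 26.3 ± 3.11%, higher in 3 of 5 mice (exact p = 0.5625), and the difference between the sites was not tested. The fewest expanded cells of a mouse were 4.

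That expanded clones more often held a Mki67 UMI was weighed against technical explanations. Counting 1 cell as 2 was argued against: in cells whose clone mates were all in the other library the excess was 37.8 points (SD 11.9; higher in 9 of 9 mice, exact p = 0.00391), against 35.1 over all expanded cells. Depth per cell was argued against as the whole cause, since the excess over single-clone cells matched on UMIs was 26.01 points (SD 9.98, 10 of 10 mice, exact p = 0.00195). Division within expanded clones is a candidate explanation, as a hypothesis found and tested on the same data.

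In cocultures with Tregs, resting genes were higher and Gzmb was lower, in cells that clustered apart: the cluster with the most cells of the library with Tregs was led by Pde2a, Cd7 and S1pr1, and it was not the one with the most cells in either library without. Cells or RNA of the added Tregs were argued against as the cause, since the Treg share read from Foxp3 was 1.90% with an upper 95% bound of 2.83%, while Gzmb was lower by 76.7%, and leaving out cells with a Foxp3 or Cd4 UMI kept 100.3% of the resting list's median (91.8 to 103). Thinning kept 121% of the median (91.4 to 147 over 18 members, taken as independent). This argues against a median carried by the deeper cells, and thinning could not test depth in other ways. A difference between single wells or libraries cannot be told apart from an effect of Tregs, since there was 1 library with Tregs.

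Other splits of the 10 tumour-bearing mice, 100 of 126 with the real one included, tested whether chance can be excluded. For the edgeR fit per mouse it can: 1 split, the real one, gave 2696 genes, and the highest other gave 350. For limma-voom per mouse and library it can as well, with 1 split at the real 2064 and the highest other at 667. That fit blocked on the library and not on the mouse. It took the values of a mouse in each library as independent, so 2064 by itself overstates the evidence over mice. Only its rank among the splits, which move whole mice, is used here. Mice of a site were pooled and share its libraries, so these splits of mice exclude chance among mice only, and the site and its pool cannot be told apart by them. For lists called per mouse with a preset correlation chance cannot be excluded, since 14 splits gave the real 10 or more and the highest other gave 11. The median of the other splits was 6 lists.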
